A study of Mus musculus and Homo sapiens with 106 samples.

How the data were processed

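Gene expression was measured by RNA-seq in 70 of the 106 samples of the series, and the other 36, from ATAC-seq and ChIP-seq, were not analysed here because no file for them was at hand. Each of the 70 libraries had a table of read counts per gene symbol, deposited by the authors, with the summary lines that HTSeq writes at its end. Per the labels' processing notes, HISAT2 2.2.1, Bowtie2 2.2.9, deepTools and HTSeq 0.12.4 were used, with the builds mm10 and hg19, and which tool made which file, the annotation and the strand setting are not stated. All values were checked to be whole numbers of at least 0, and 0 of 55 pairs of libraries within a group were identical. The tables are tab-separated without a header under a comma-separated file type, so their unit is recorded as other in the table of units although they hold counts, and a range test that covers counts was made only by the check just named. The mouse tables held 23337 genes and those of human cells 26364. Symbols are as deposited, some of them older names (Irg1 is now Acod1).

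Per the labels' protocols, bone marrow was grown for 7 days in medium with 30% L929 supernatant, agonists were given for 4 h, topotecan was added 1 h before them, RNA was taken with TRIzol, and libraries came either from a Takara pico-input total RNA kit or from polyA selection. The word takara stands in the titles of 12 libraries from FL and KO macrophages, and the labels do not name the kit of the others. Nothing in the labels states that replicates came from separate animals or cultures, so every p-value measures the spread between these samples.

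Reads that HTSeq assigned to no gene, to several genes or to no unique place were left out of library sizes and tests. The share of reads in no gene was 37.3 to 48.0% in the takara-labelled libraries, 11.2 to 13.2% in the other FL and KO libraries, 8.5 to 14.0% in the WT libraries, 34.7 to 85.9% in the RAW264.7 libraries and 59.4 to 69.1% in the human libraries. Counts in genes (M, mega) came to 4.44 to 7.53 M per takara-labelled library, 14.48 to 30.03 M per other FL or KO library, 14.64 to 47.72 M per WT library, 1.51 to 4.28 M per RAW264.7 library and 2.07 to 4.78 M per human library.

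Libraries were grouped by the labels into 31 groups and fitted in 5 sets: 12 takara-labelled FL and KO libraries, 16 other FL and KO libraries, 24 WT libraries, 12 RAW264.7 libraries and 6 human libraries. All groups of a set shared 1 estimate of the spread. Genes were kept where enough libraries reached a CPM equal to 10 counts at the median library size and the total reached 15 counts, and library sizes were scaled by the trimmed mean of M values (TMM), written for this work in R. The 39 comparisons were tested with limma-voom (limma 3.58.1, R 4.3.3, package data.table in version 1.17.8) with a count offset of 0.5, and p-values were adjusted by the Benjamini-Hochberg method within each comparison, so that a gene is called where its adjusted p is under 0.05. The planned test was the edgeR quasi-likelihood test, and limma-voom was used instead of it because the recorded unit rules out count models. For the same reason the planned DESeq2 alternatives were not run. CPM values are TMM-scaled, given as mean ± SD, and log2 fold changes come from the fit with their standard error (SE).

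The groups, comparisons, gene lists, named-gene rule and alternatives named in the plan were all fixed before the data were examined. The rule named Top1, the 6 largest rises and 6 largest falls among called genes with a mean of at least 10 CPM in a group, groups that did not overlap and a symbol that is not a bare gene model, and up to 4 members with the smallest p from each of 20 lists that held 367 genes in all. The lists were cytokines, chemokines, interferon and interferon-stimulated genes, immediate early and feedback genes, the NF-kappaB pathway, inflammatory effectors, TLR signalling, topoisomerases, SWI/SNF subunits, p53 targets and DNA damage, cell cycle, glycolysis and hypoxia, cholesterol synthesis, macrophage identity, heat shock and stress, and markers of neutrophils, dendritic cells, lymphocytes, stroma, and erythroid and mast cells. The topoisomerase list also held Tdp1 and Tdp2, which are not topoisomerases, and the stromal list held endothelial genes. Each list was tested with limma's fry, adjusted over the lists of a comparison. This test asks whether the members move, on balance, in a direction and does not compare a list with other genes. Members were also counted with p-values adjusted over the list alone. Genes induced by an agonist were defined in libraries not used in the comparison (adjusted p under 0.05 and a log2 fold change of at least 1) and followed as a set. A fold against a group at 0 counts is given as a lower bound from a floor of 3 counts over the group, which covers counting error only.

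Replicate numbers were checked for pairing by correlating each library's deviations from its group means. In the LPS response of WT cells, the same-number correlations were 0.533, 0.734, 0.51 and 0.562, and the highest with another number -0.043, 0.36, 0.282 and 0.398. In topotecan with LPS against LPS they were 0.195, 0.706, 0.6 and 0.545, and the highest with another number 0.551, -0.012, 0.4 and 0.303. So these numbers pair the samples, except that replicate 1 of topotecan with LPS went closer with another number. The blocked fits called 6619 genes against 4988 without the block and 0 against 0. In the other comparisons at least 1 group held only 2 libraries. For most of them neither the labels nor so few pairs show whether the numbers pair the samples. Against untreated WT, same-number correlations were -0.049 and -0.172 with FSL, -0.12 and -0.242 with Imiquimod, and -0.126 and -0.147 with topotecan alone. The highest correlation with another number was 0.417 to 0.525 there. These values argue against pairing by number with the untreated WT libraries, so blocked counts that use them may tie unlike samples. The labels list untreated WT 1 to 4 with the LPS libraries, and 5 and 6 with FSL, Imiquimod and topotecan alone. They do not state separate series. Scaling factors were 0.918 to 1.145 in untreated WT 1 to 4, and 1.241 and 1.248 in 5 and 6. Comparisons with untreated WT pooled all 6, and the topotecan difference with LPS used libraries of both kinds. Alternatives were median-of-ratios scaling, no low-count filter, the replicate block, other WT controls, a stricter threshold for induced genes, takara-labelled and other libraries in 1 fit, and each replicate left out in turn. Added after the data were seen were limma with a trend on log2(CPM + 2), the share of reads in no gene as a covariate for RAW264.7, and a block over the compared groups only.

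For 1 comparison from each of the 5 sets, the fit was tested on simulated data drawn from the real means, spreads within groups and library sizes. Apart from the changed genes, each gene had the same mean in all groups of a set, and libraries were drawn independently. The simulated data thus held no agonist responses, pairing or differences in background. Recovery and false calls in the real libraries may differ from those given here. The list tests and the other comparisons were not simulated. Of the genes given an absolute log2 fold change of 1 and of 2, the fit recovered 49% and 64.2% for KO against FL with LPS in the takara-labelled libraries (11618 genes) and 23.2% and 61% for untreated KO against FL in the others (13439 genes). It recovered 19.4% and 69.4% for topotecan with LPS (13378 genes), 2.1% and 33.7% for Top1WT against TagRFP with LPS in RAW264.7 (17103 genes), and 43.8% and 71.4% for Top1Y725F against Top1WT in the human cells (14740 genes). False calls numbered 1 to 6 per simulation. Gene lengths came from the mouse RefSeq table by symbol and gave a length to 99.3 to 99.4% of tested genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.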

Results

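The study asks how topoisomerase 1 (Top1), an enzyme that relieves DNA supercoiling, shapes the gene program that macrophages switch on through Toll-like receptors (TLRs). Expression of all genes was measured in 70 RNA-seq libraries. Macrophages grown from mouse bone marrow came from mice with an unrecombined floxed Top1 gene (FL), from mice that lose it through Cre expressed from the lysozyme locus (KO), and from C57BL6/J mice (WT). The mouse macrophage line RAW264.7 expressed TagRFP, a red fluorescent protein, normal Top1 (Top1WT) or Top1Y725F, a mutant that lacks the tyrosine needed to cut DNA. A human HEK293T line without its own Top1, called E3C3, expressed the same Top1WT or Top1Y725F. Cells were left untreated or were given LPS (a TLR4 agonist), PolyIC (TLR3), Pam3CSK4 or FSL (TLR2) or Imiquimod (TLR7), and some WT cells were given topotecan, an inhibitor that traps Top1 on DNA. Each group held 2 libraries, except 6 for untreated WT, 4 for WT with LPS and 4 for WT with topotecan and LPS. Counts in genes ranged from 1.51 M in RAW264.7 to 47.72 M in WT (M, mega).

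Untreated KO and FL macrophages differed in the takara-labelled libraries. Targets of p53 and stress genes rose on balance, while genes of cholesterol synthesis and of macrophage identity fell on balance. The comparison asks how the genotypes differ before any agonist. Of 12014 genes tested, limma-voom called 1289, of which 496 were higher and 793 lower in KO. Top1 itself stood at 101 to 167 CPM in the 6 KO libraries and at 106 to 233 CPM in the 6 FL libraries. Untreated, it was 105 ± 5.78 CPM in KO and 109 ± 3.17 CPM in FL (SD, n = 2 each, adjusted p 0.847). A count over the whole gene does not show whether the deleted part was lost. Among 23 p53 targets, 11 rose, 1 fell and 11 did not pass, and 14 rose and 1 fell when adjusted over the list alone (fry adjusted p 0.000387). Gadd45a rose from 16.6 ± 2.95 to 70.4 ± 8.75 CPM (log2 fold change 2.10, SE 0.21, adjusted p 3.42e-06). Mdm2 rose from 155 ± 13.6 to 320 ± 19.2 CPM and Cdkn1a from 45.5 ± 7.94 to 105 ± 2.84 CPM, while Sesn1 fell (log2 fold change -1.52). Of 19 cholesterol genes, 0 rose, 12 fell and 7 did not pass, with 1 and 16 adjusted over the list alone (fry adjusted p 0.00176). Insig1 (log2 fold change -1.84) and Srebf2 (-0.97) were among those that fell. Of 18 macrophage identity genes, 10 fell, 1 rose and 7 did not pass, with 13 and 1 adjusted over the list alone (median -0.83, fry adjusted p 0.000387). Lyz2, the gene that carries Cre in this line, fell from 6740 ± 246 to 1250 ± 228 CPM (log2 fold change -2.43), C1qa from 407 ± 41.4 to 85.7 ± 15.9 CPM and Apoe from 5470 ± 444 to 2440 ± 36.3 CPM. Cebpb was the member that rose.

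The other lists were tested in the same untreated cells. Of 10 heat shock and stress genes, 4 rose (Asns, Hmox1, Ddit3, Atf4), 1 fell (Hspa5) and 5 did not pass, with 4 and 2 adjusted over the list alone (fry adjusted p 0.011). Hmox1 rose from 178 ± 4.03 to 554 ± 46.4 CPM. Of 33 interferon genes, 10 rose, 1 fell and 22 did not pass, with 14 and 2 adjusted over the list alone (fry adjusted p 0.115), and Oasl1 rose from 6.56 ± 4.17 to 42.2 ± 7.45 CPM. Of 24 TLR signalling genes, 6 fell, 0 rose and 18 did not pass, with 7 and 1 adjusted over the list alone (fry adjusted p 0.0239). Tlr2 fell by 1.61 and Cd14 fell by 1.26 on the log2 scale. Of 19 NF-kappaB genes, 5 fell and 1 rose, with 8 and 1 adjusted over the list alone (fry adjusted p 0.0266), and Nfkbiz fell by 1.71. Of 17 cytokines, 2 rose (Csf1, Il1rn), 0 fell and 15 did not pass, the same numbers adjusted over the list alone (median 0.53, fry adjusted p 0.0062), with Csf1 from 12.5 ± 8.5 to 68.5 ± 15 CPM. Among 13 stromal markers, 3 rose (Kdr, Pecam1, Cdh5), 0 fell and 10 did not pass, with 6 adjusted over the list alone (fry adjusted p 0.13). The 3 that rose are endothelial genes. The remaining lists had fry adjusted p-values of 0.895 (chemokines), 0.494 (immediate early), 0.422 (inflammatory effectors), 0.575 (topoisomerases), 0.331 (SWI/SNF), 0.424 (cell cycle), 0.13 (glycolysis), 0.494 (neutrophil, with a median of -1.96 and 3 of 11 members above 0), 0.304 (dendritic), 0.175 (lymphocyte) and 0.188 (erythroid and mast cell). The largest rises included Apol9b, at least 51.1-fold higher than the floor in FL, Pou3f1 (0.395 ± 0.072 to 20.3 ± 0.85 CPM) and H2-Q6 (1.34 ± 0.2 to 53.6 ± 7.5 CPM), which belongs to a family of near copies and is uncertain. The largest falls included Abca9 (47.4 ± 3.87 to 3.09 ± 0.793 CPM) and Itgax (111 ± 51.1 to 12.3 ± 5.94 CPM). Without FL 1, FL 2, KO 1 or KO 2, the count of called genes was 736, 652, 487 and 682.

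**Figure D1:**
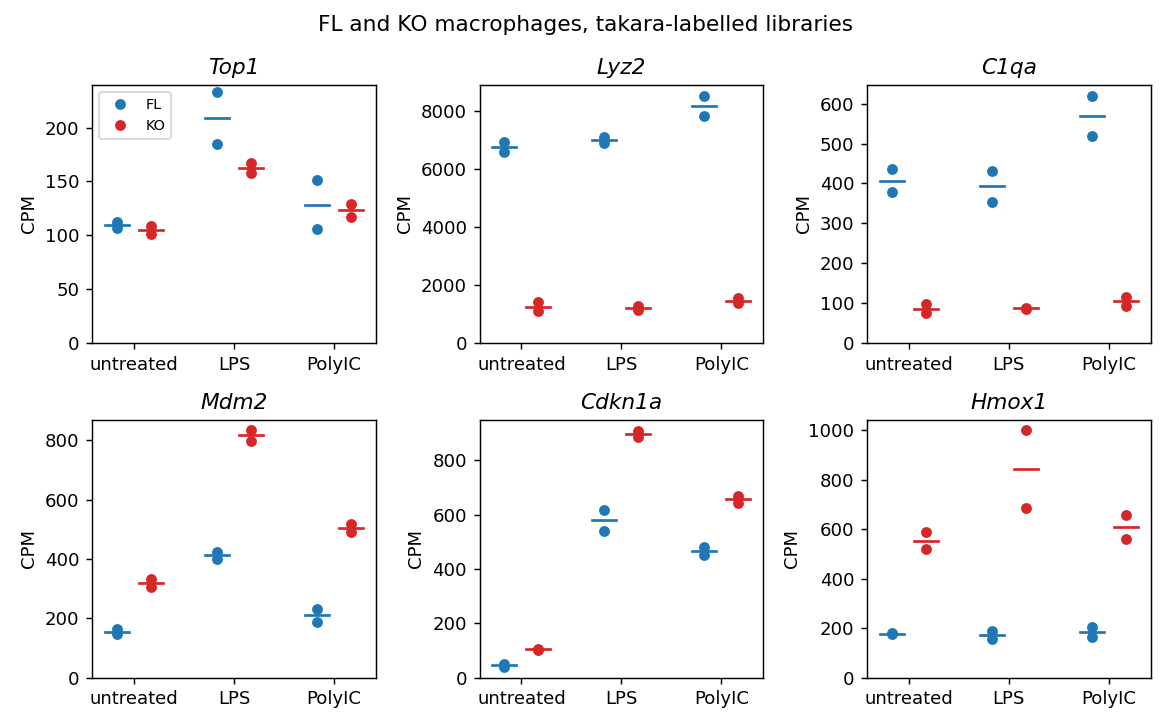
TMM-scaled CPM of 6 genes in the 12 takara-labelled libraries of FL (blue) and KO (red) macrophages, untreated or with LPS or PolyIC, with a point per library and a bar at the mean of 2. Lyz2 and C1qa were lower in KO and Mdm2, Cdkn1a and Hmox1 higher under all 3 conditions, while Top1 overlapped or lay close.

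**Figure D2:**
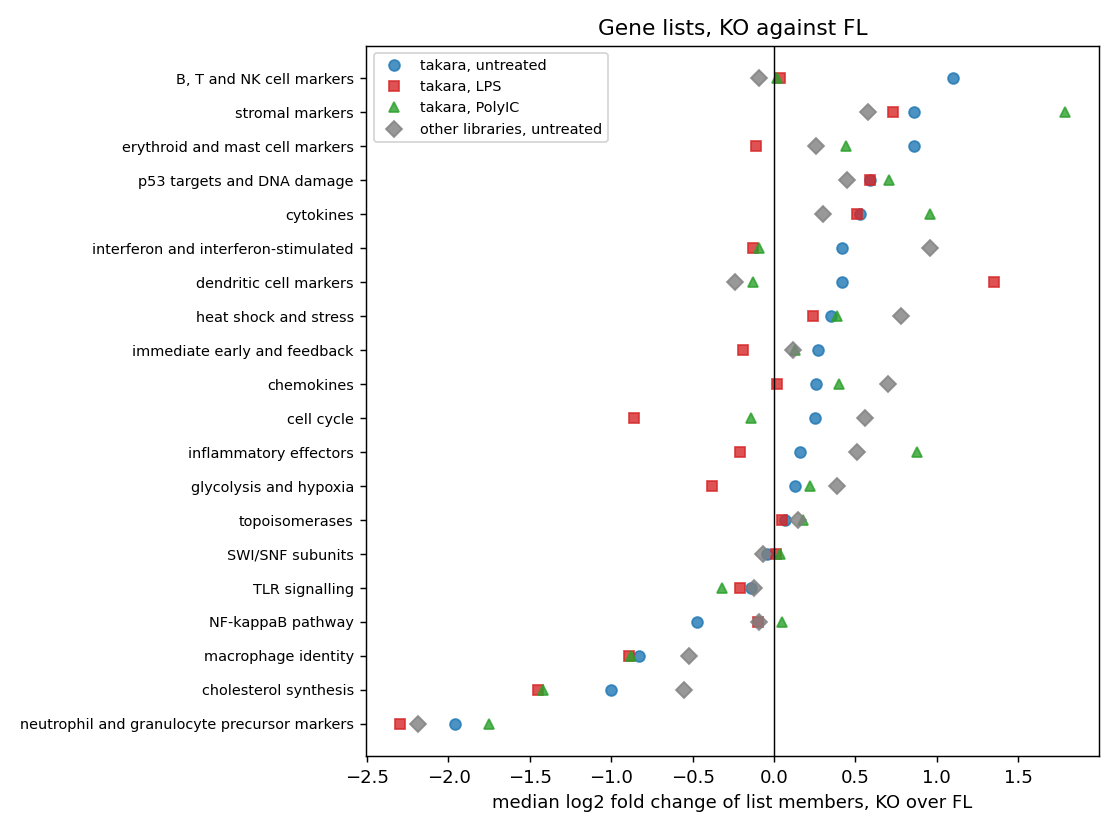
Median log2 fold change, KO over FL, of the measured members of each of 20 gene lists, for the 3 takara-labelled comparisons (coloured) and for the untreated cells of the other libraries (grey). Cholesterol synthesis and macrophage identity genes had medians below 0 and p53 targets above 0 in all 4.

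With LPS, inflammatory genes differed between KO and FL macrophages in both directions. The comparison asks how the genotypes differ under LPS. limma-voom called 1630 genes, 590 higher and 1040 lower in KO. Of 17 cytokines, 7 rose, 2 fell (Il12b, Il10) and 8 did not pass, with 8 and 3 adjusted over the list alone (fry adjusted p 8.93e-06). Il23a rose from 0.615 ± 0.453 to 43.1 ± 23.6 CPM (log2 fold change 5.78, SE 1.13, adjusted p 0.00173), Il1a from 123 ± 3.03 to 406 ± 67.4 CPM and Il6 from 170 ± 8.65 to 378 ± 26.6 CPM. Of 16 chemokines, 4 rose (Cxcl3, Ccl22, Cxcl1, Cxcl2), 5 fell (Cxcl9, Ccl12, Ccl4, Ccl5, Ccl3) and 7 did not pass, with 5 and 6 adjusted over the list alone (fry adjusted p 0.0822). Cxcl1 rose from 68.4 ± 17.4 to 438 ± 132 CPM, and Cxcl9 fell from 194 ± 40.5 to 43.2 ± 9.26 CPM. Of 33 interferon genes, 3 rose, 8 fell and 22 did not pass, with 3 and 10 adjusted over the list alone (fry adjusted p 0.408). Ifnb1 rose from 1.79 ± 0.445 to 36.7 ± 14.3 CPM, while Irf8 fell from 887 ± 204 to 134 ± 44.9 CPM (log2 fold change -2.73, SE 0.18, adjusted p 5.77e-08). Of 19 glycolysis genes, 9 fell and 1 rose, with 10 and 2 adjusted over the list alone (fry adjusted p 0.0208), and Pfkfb3 fell from 1410 ± 118 to 745 ± 249 CPM. Slc7a11 rose from 208 ± 80 to 958 ± 139 CPM, Ptges from 115 ± 5.85 to 323 ± 54.5 CPM, and Jun fell from 239 ± 33.5 to 85.7 ± 3.65 CPM. Of 19 cholesterol genes, 13 fell and 0 rose, with 15 and 0 adjusted over the list alone (fry adjusted p 0.000791), and of 18 macrophage identity genes, 13 fell and 0 rose, with 13 and 1 adjusted over the list alone (fry adjusted p 0.000233). Neutrophil markers had a median of -2.30, with 2 of 11 members above 0, and stromal markers 0.73, with 12 of 13 above 0. Of 23 p53 targets, 5 rose (Phlda3, Pmaip1, Sesn2, Mdm2, Cdkn1a), 0 fell and 18 did not pass, with 11 and 1 adjusted over the list alone (fry adjusted p 0.000665), and these 5 had also risen untreated. Immediate early genes rose in 5 of 19 cases and fell in 7, with 6 and 7 adjusted over the list alone, a median of -0.19 and a mean of 0.21 (fry adjusted p 0.855). Inflammatory effectors rose in 5 of 19 and fell in 5, with 6 and 6 adjusted over the list alone, and their median of -0.21 lay below 0 while the test pointed up (fry adjusted p 0.623). Without KO 1 with LPS, 784 genes were called.

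With PolyIC, limma-voom called 1638 genes, 777 higher and 861 lower in KO. Of 17 cytokines, 7 rose and 1 fell (Il10), the same numbers adjusted over the list alone (fry adjusted p 1.76e-05). Of 16 chemokines, 8 rose and 0 fell, with 8 and 2 adjusted over the list alone (fry adjusted p 0.00456), among them Ccl22 (4.41 ± 0.89 to 40.1 ± 2.5 CPM) and Ccl2 (64.9 ± 1.79 to 239 ± 1.24 CPM). Of 19 inflammatory effectors, 11 rose and 2 fell, with 12 and 4 adjusted over the list alone (fry adjusted p 0.00456). Mmp13 rose from 63.7 ± 6.85 to 255 ± 10.2 CPM. p53 targets rose in 13 of 23 cases and fell in 1, with 14 and 2 adjusted over the list alone (fry adjusted p 0.000198), with Pmaip1 from 10 ± 2.74 to 73 ± 4.97 CPM, and cholesterol genes fell in 16 of 19 and rose in 0, with 18 and 0 adjusted over the list alone (fry adjusted p 0.000326). Of 13 stromal markers, 9 rose and 0 fell, with 11 and 0 adjusted over the list alone (fry adjusted p 0.0355), with Dcn from 13.3 ± 1.85 to 49.8 ± 0.228 CPM. TLR signalling genes fell in 8 of 24 cases and rose in 1, with 10 and 3 adjusted over the list alone (fry adjusted p 0.00843), with Cd14 from 937 ± 20.6 to 456 ± 6.76 CPM. Of 5 dendritic cell markers, 2 rose and 0 fell, the same numbers adjusted over the list alone, with a median of -0.13 while the test pointed up (fry adjusted p 0.0441). Without FL 1, KO 1 or KO 2 with PolyIC, 827, 713 and 934 genes were called.

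In FL cells the agonists acted broadly. limma-voom called 5577 genes with LPS (2905 higher, 2672 lower) and 3473 with PolyIC (1941 higher, 1532 lower). With LPS, all 33 interferon genes and all 19 NF-kappaB genes rose, by all genes tested and adjusted over the list alone. Rsad2 rose from 76.6 ± 23 to 11800 ± 772 CPM, and Il6 rose at least 438-fold over the floor. Top1 rose from 109 ± 3.17 to 209 ± 34 CPM with LPS (log2 fold change 0.93, SE 0.16, adjusted p 8.2e-05) and did not pass with PolyIC (adjusted p 0.408).

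The test of the difference between the responses of KO and FL asked which genes respond unequally. For LPS, limma-voom called 285 genes, 123 with a higher and 162 with a lower response in KO. Among 33 interferon genes, 9 had a lower response, 1 a higher response (Irf1) and 23 did not pass, with 18 and 2 adjusted over the list alone (fry adjusted p 0.186). For Irf8 the difference was -2.46 on the log2 scale (SE 0.25, adjusted p 7.25e-05) and for Oasl1 -1.85. Oasl1 and other interferon genes were already higher in untreated KO. A lower response of such a gene need not mean a lower level with the agonist. Tlr2, lower at rest in KO, responded more (2.32, SE 0.19, adjusted p 5.53e-06), as did Cd14 (1.42), while Jun responded less (-2.05). For PolyIC 38 genes were called, 22 higher and 16 lower, with 5 interferon genes lower (15 adjusted over the list alone), Oasl1 among them (-2.01). Without FL 1, FL 2, KO 1 or KO 2 untreated or KO 1 with LPS, the LPS count was 159, 141, 109, 145 and 183. The PolyIC count was 14, 11, 3 and 10 without FL 1, FL 2, KO 1 or KO 2 untreated, and 17, 12 and 10 without FL 1, KO 1 or KO 2 with PolyIC. With the replicate number as a block, the LPS count was 480 and the PolyIC count 107.

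Genes that LPS induced in WT cells were followed as a set in KO. With LPS, of 1665 such genes measured, 371 (22.3%) were lower and 175 (10.5%) higher in KO, against 6.5% and 4.0% of the other genes. Their median log2 fold change was -0.16 and the mean -0.05 (fry adjusted p 0.233). Without KO 2 with LPS the median was -0.24 (adjusted p 0.0126), and without KO 1 with LPS it was -0.06 (adjusted p 0.802), with 163 genes lower and 142 higher. The medians were -0.01 with PolyIC (mean 0.14) and -0.01 untreated (mean 0.03), so median and mean differ in sign there. Without FL 1, FL 2 or KO 1 with PolyIC, the PolyIC median was 0.00, 0.02 and 0.02, and without KO 1 untreated the untreated median was 0.02.

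The other FL and KO libraries, with Pam3CSK4, FSL and Imiquimod, showed few genes past the threshold between genotypes. limma-voom called 0 genes untreated (756 at an unadjusted p under 0.05), 0 with Pam3CSK4 (1119) and 0 with FSL (1035), and limma with a trend on log2 CPM also called 0 in each. With Imiquimod 4 genes were higher in KO (974 at an unadjusted p under 0.05), namely Emcn, Plvap, Angpt2 and Crim1, each at an adjusted p of 0.0368, and limma with a trend called 7. With the replicate number as a block, the counts were 10 untreated, 12 with Pam3CSK4, 17 with FSL and 74 with Imiquimod. Plvap rose from 20.6 ± 1.71 to 115 ± 7.99 CPM and Emcn from 7.41 ± 0.537 to 50.3 ± 5 CPM. Top1 stood at 114 ± 13.4 CPM in KO and 140 ± 42.2 CPM in FL, untreated (adjusted p 0.932). The directions of the main lists were as in the takara-labelled cells, with medians of -0.55 for cholesterol genes, -0.52 for macrophage identity genes and 0.45 for p53 targets, and 0 members of these lists passed, also adjusted over the list alone. Lyz2 was -1.46 (SE 0.46, adjusted p 0.834) and Cdkn1a 0.93 (SE 0.51, adjusted p 0.874). Without FL 3 untreated 3 genes were called, and without FL 2 with FSL 11 genes. Without FL 1, FL 2, KO 1 or KO 2 with Imiquimod the count was 0, 2, 0 and 0. Genes induced in WT cells had medians of -0.06 with Pam3CSK4, -0.20 with FSL and -0.24 with Imiquimod (fry adjusted p 0.916, 0.802 and 0.802). No WT library had Pam3CSK4, so its value is for the genes that FSL induced in WT cells. The Pam3CSK4 median was 0.12 and 0.23 without FL 2 or KO 2 with Pam3CSK4, and it was -0.16 and -0.26 without FL 1 or KO 1. Without FL 1, FL 2, KO 1 or KO 2 with FSL the FSL median was -0.24, -0.13, -0.42 and 0.09. Without FL 1, FL 2, KO 1 or KO 2 with Imiquimod the Imiquimod median was -0.95 (fry adjusted p 0.0963), 0.40, -0.32 and -0.24.

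Of 1287 genes called untreated in the takara-labelled libraries and measured in the others, 1143 (88.8%) had the same sign, against 64.6% of genes not called. This held for 401 of 494 higher and 742 of 793 lower genes. Across these genes, which are not independent replicates, Pearson's r was 0.83 and Spearman's rho 0.79. The median absolute log2 fold change was 0.86 in the takara-labelled libraries and 0.46 in the others, and the median SE was 0.18 and 0.36. These genes were selected by their calls in the takara-labelled libraries, which alone makes their fold changes smaller elsewhere and can make their SE larger there. For 66.7% of them the takara-labelled fold change lay within the 95% interval of that in the other libraries. A fit of both kinds of library with the takara label as a factor called 48 genes.

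**Figure D3:**
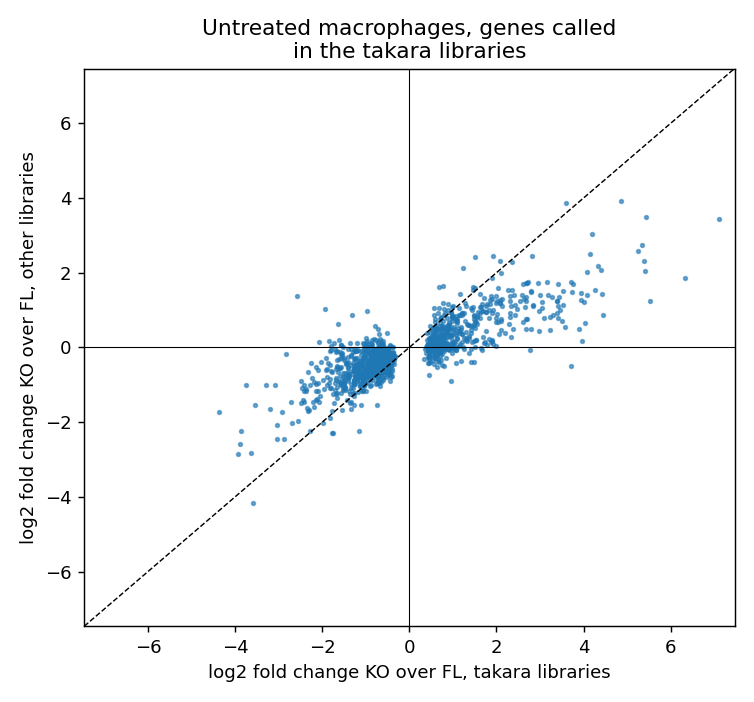
Log2 fold change, KO over FL in untreated cells, of the 1287 genes called in the takara-labelled libraries (x axis) against the same genes in the other libraries (y axis), with a point per gene and a dashed line at equality. Most points share their sign and lie nearer to 0 on the y axis.

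In FL cells, limma-voom called 978 genes with Pam3CSK4 (609 higher, 369 lower), 1021 with FSL (580 higher, 441 lower) and 59 with Imiquimod (54 higher, 5 lower). All 19 NF-kappaB genes rose with Pam3CSK4 and with FSL, and 11 of 19 with Imiquimod, 19 in each case adjusted over the list alone. Tnf rose from 23.2 ± 7.03 to 2630 ± 888 CPM with Pam3CSK4, and Irg1, the gene of itaconate synthesis, from 6.79 ± 0.597 to 2890 ± 473 CPM with FSL. Rgs2 fell from 237 ± 52.9 to 10 ± 5.32 CPM with Pam3CSK4. Pam3CSK4 against FSL called 0 genes by limma-voom (268 at an unadjusted p under 0.05) and 0 by limma with a trend. The differences between KO and FL in these responses were also 0 by both (46, 108 and 33 at an unadjusted p under 0.05). Without FL 3 or FL 4 untreated the counts were 188 and 223 for Pam3CSK4, 271 and 237 for FSL and 15 and 0 for Imiquimod. Without treated FL 1 or FL 2 they were 260 and 70, 157 and 647, and 599 and 8. Without FL 2 with FSL, 3 genes differed between Pam3CSK4 and FSL and 1 gene between the genotypes in the FSL response.

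In WT macrophages, limma-voom called 4988 of 13765 genes with LPS, 2579 higher and 2409 lower, of which 1771 rose and 1778 fell at least 2-fold. The balance turned with the replicate number as a block (3228 higher, 3391 lower). All 17 cytokines and all 19 NF-kappaB genes rose, as did 16 of 17 chemokines, 32 of 33 interferon genes, 18 of 19 inflammatory effectors and 15 of 24 TLR signalling genes. Adjusted over the list alone these counts were 17, 19, 16, 32, 18 and 16. Il6 rose from 8.13 ± 11.9 (n = 6) to 1470 ± 1120 CPM (n = 4), Il12b from 4.41 ± 5.59 to 1260 ± 839 CPM and Il23a from 0.315 ± 0.372 to 129 ± 26 CPM. Nos2 rose from 2.89 ± 3.03 to 1270 ± 501 CPM (log2 fold change 9.92, SE 0.71, adjusted p 3.09e-09), and Tnf from 59.3 ± 27.1 to 5520 ± 2830 CPM. Ccl5 rose from 10.5 ± 4.28 to 1510 ± 196 CPM, Gbp5 from 13.2 ± 12.5 to 3040 ± 991 CPM and Icam1 from 110 ± 15.3 to 4300 ± 950 CPM. Tlr2 rose from 174 ± 74.5 to 1680 ± 320 CPM and Hk2 from 81.1 ± 19.8 to 372 ± 110 CPM. Cnr2 fell from 69.7 ± 18.5 to 0.788 ± 0.557 CPM, Bmf from 32.9 ± 16.7 to 0.498 ± 0.569 CPM and Cebpa from 422 ± 229 to 33.9 ± 17.4 CPM. Of 23 cell cycle genes, 13 fell, 1 rose (Mki67) and 9 did not pass, with 14 and 2 adjusted over the list alone (fry adjusted p 0.00818). Of 23 p53 targets, 6 rose and 7 fell, with 7 and 7 adjusted over the list alone, and their median of -0.25 lay below 0 while the test pointed up (fry adjusted p 0.0261). Cdkn1a rose from 109 ± 44.4 to 2460 ± 998 CPM. Top1 rose from 114 ± 47.2 to 257 ± 78.4 CPM (log2 fold change 1.23, SE 0.30, adjusted p 0.00331).

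FSL in WT cells called 1067 genes (607 higher, 460 lower) and Imiquimod 127 (108 higher, 19 lower). NF-kappaB genes rose in 18 of 19 cases with FSL and 17 of 19 with Imiquimod, 19 in each case adjusted over the list alone. Cytokines rose in 11 of 17 cases with FSL and 2 of 17 with Imiquimod, 12 and 6 adjusted over the list alone. Cxcl1 rose from 6.9 ± 4.24 CPM to 462 ± 315 CPM with FSL and to 144 ± 65.7 CPM with Imiquimod, and Socs3 from 11.1 ± 1.66 to 268 ± 115 CPM with Imiquimod. Top1 did not pass with either. Without WT 1 or WT 2 with FSL the count was 192 and 671, and without WT 1 or WT 2 with Imiquimod it was 47 and 20. Against untreated replicates 5 and 6 alone the counts were 304 and 38, and against replicates 1 to 4 Imiquimod called 211. With the replicate number as a block they were 4559 and 3161, though same-number correlations with untreated WT were negative in both comparisons.

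Topotecan in WT cells left no gene past the threshold in the fit without a block for the replicate number, while some blocked fits called genes. The comparison asks whether blocking the enzyme mimics its loss. limma-voom called 0 genes with LPS (176 at an unadjusted p under 0.05), 0 with FSL (22), 0 with Imiquimod (15) and 0 without agonist (247), and limma with a trend called 0 in each. The differences between topotecan effects with and without agonist were also 0 by both tools (90, 38 and 55 at an unadjusted p under 0.05). With the replicate number as a block, the counts were 0 with each agonist and 1937 without agonist. The differences were then 722 with LPS, 30 with FSL and 38 with Imiquimod. Same-number correlations of topotecan alone with untreated WT were -0.126 and -0.147, so blocked counts that use these groups may tie unlike samples. With a block over the compared groups only, chosen after seeing the data, the topotecan counts were 0 with LPS, 7 with FSL and 451 with Imiquimod (116 higher, 335 lower). Genes induced by the agonist in FL cells had median log2 fold changes with topotecan of -0.08 with LPS, -0.10 with FSL and -0.36 with Imiquimod, and 0.06 without agonist. The value without agonist is for the genes that LPS induced in FL cells. Without WT 3 with LPS or WT 1 with topotecan and LPS, the LPS median was 0.06 and 0.03. Without WT 1 with FSL or WT 2 with topotecan and FSL, the FSL median was 0.15 and 0.13. Without WT 1 or WT 2 with Imiquimod, or WT 1 or WT 2 with topotecan and Imiquimod, the Imiquimod median was -0.43, -0.31, -0.21 and -0.48. Without agonist the median ran from 0.03 (without WT 1 with topotecan) to 0.09 (without untreated WT 3), and was 0.29 with the replicate number as a block (fry adjusted p 0.186). With the block over the compared groups, the FSL median was -0.08 (fry adjusted p 0.0211, against 0.802 without it). The LPS median was -0.06 (0.253) and the Imiquimod median -0.35 (0.441), with 32 of the Imiquimod-induced genes called lower. In the LPS libraries, 1689 genes of at least 100 kb had a median of -0.22 and the other genes 0.02, a difference of -0.24. Per library, the median log2 CPM of long genes minus that of the others was -0.72 ± 0.24 with topotecan (mean ± SD, n = 4) and -0.47 ± 0.07 without (n = 4). The exact two-sided permutation p over 70 splits, which ignores the replicate numbers, was 0.086, where the smallest possible is 0.029. The value was lower with topotecan in 4 of 4 pairs by number. A paired test that flips the signs of these differences cannot go below 0.125. Without WT 3 with topotecan and LPS the difference was -0.30 (p 0.029, the same exact permutation test, which ignores the pairs). Without WT 4 with topotecan and LPS it was -0.16 (p 0.143, the same test). The same difference was -0.05 with FSL, -0.11 with Imiquimod and -0.06 without agonist. For KO against FL in the takara-labelled libraries it was -0.011 with LPS, -0.027 with PolyIC and -0.062 untreated. For the response to FSL without topotecan it was -0.219 in FL cells and -0.033 in WT cells. A shift near that of topotecan with LPS thus also arose between libraries without the drug. Across 11820 genes, which are not independent, the topotecan effect with LPS and the KO effect with LPS had a Pearson r of 0.222 and a Spearman rho of 0.211, and Pearson's r ranged from 0 to 0.298 without 1 library.

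In RAW264.7 cells with TagRFP, limma-voom called 2119 of 18289 genes with LPS, 1294 higher and 825 lower, and under median-of-ratios scaling 1713 higher and 631 lower. The balance turned in limma with a trend (1232 higher, 1650 lower), without the low-count filter (1151 and 1521) and with the share of reads in no gene as a covariate (46 and 100), of which the first and last were chosen after seeing the data. Cytokines rose in 13 of 17 cases, NF-kappaB genes in 15 of 19 and cell cycle genes in 18 of 23, with 13, 17 and 19 adjusted over the list alone. Tnf rose from 471 ± 39.3 to 4050 ± 87.4 CPM, Lif from 33 ± 3.99 to 1480 ± 197 CPM and Cxcl2 from 469 ± 37.2 to 7260 ± 759 CPM. Top1 rose from 465 ± 17.7 to 1000 ± 57.4 CPM. Without TagRFP 1 or TagRFP 2 untreated 522 and 903 genes were called, and without TagRFP 1 or TagRFP 2 with LPS 630 and 627. The share of reads in no gene was 66.2 ± 3.6% in untreated TagRFP cells and 38.4 ± 5.2% with LPS, so these libraries also differed in background.

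Expressing Top1WT or Top1Y725F raised Top1 far above the control, to 48700 ± 26300 and 75500 ± 16800 CPM untreated and to 59500 ± 1760 and 54700 ± 6360 CPM with LPS. Untreated, Top1WT against TagRFP called 29 genes (11 higher, 18 lower), Top1Y725F against TagRFP 48 (5 higher, 43 lower) and Top1Y725F against Top1WT 6 (0 higher, 6 lower). The proliferation genes Hmmr (9.03 ± 6.58 to 58.9 ± 10.4 CPM) and Cenpf rose with Top1WT. Bnip3 was 20.4 ± 8.11 CPM with Top1Y725F against 130 ± 37.9 CPM in TagRFP and 133 ± 48 CPM with Top1WT, and Ptgs2 was lower with Top1Y725F than with Top1WT (978 ± 452 against 3450 ± 794 CPM). Without TagRFP 1, TagRFP 2, Top1WT 1 or Top1WT 2, the Top1WT count was 1, 3, 3 and 6. Without TagRFP 1, TagRFP 2, Top1Y725F 1 or Top1Y725F 2, the Top1Y725F count was 5, 3, 23 and 3654. For Top1Y725F against Top1WT it was 1, 2 and 373 without Top1WT 1, Top1WT 2 or Top1Y725F 2. The 3 counts were 12, 18 and 3 without the low-count filter, and 18, 2 and 11 with the share of reads in no gene as a covariate, chosen after seeing the data.

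With LPS, more genes were called against TagRFP. Top1WT against TagRFP called 1801 genes (737 higher, 1064 lower), or 575 higher and 1474 lower under median-of-ratios scaling, and Top1Y725F against TagRFP called 9520 (5903 higher, 3617 lower). The balance for Top1WT turned in limma with a trend (2076 higher, 1105 lower) and without the low-count filter (1767 and 979). Top1Y725F against Top1WT called 6, with Il1a higher and Ptma, Lyz2, Hmgb2, Rps29 and Hmox1 lower. With Top1Y725F, 29 of 33 interferon genes, 17 of 19 NF-kappaB genes, 21 of 23 cell cycle genes and 15 of 19 glycolysis genes were lower than in TagRFP, with 29, 17, 22 and 15 adjusted over the list alone. Some markers of other cell types were higher, with 7 of 12 lymphocyte markers and 8 of 13 stromal markers, 9 and 8 adjusted over the list alone. Of all 18289 genes tested, 5903 were higher and 52.1% were called in either direction. With Top1WT, 8 of 19 NF-kappaB genes were lower and 0 higher, with 10 and 0 adjusted over the list alone (fry adjusted p 0.00647). Lpl was 338 ± 35.9 CPM in TagRFP, 30 ± 13 CPM with Top1WT and 20.5 ± 1.56 CPM with Top1Y725F. The share of reads in no gene was 38.4 ± 5.2% in TagRFP, 67.9 ± 9.6% with Top1WT and 83 ± 4.1% with Top1Y725F, and 471 genes of families silent in macrophages summed to 57.5 ± 20.4, 343 ± 156 and 807 ± 210 CPM. With the share of reads in no gene as a covariate, chosen after seeing the data, the 3 counts were 7, 1 and 0. The TagRFP libraries with LPS had 34.7 and 42.1% of reads in no gene, and every other RAW264.7 library at least 61.2%. Against TagRFP the covariate so goes with the compared groups. It would also remove an effect of the construct, so the lower counts do not show which of them made the calls. LPS-induced genes had a median log2 fold change of -0.20 with Top1WT (mean 0.09, fry adjusted p 0.203) and -0.50 with Top1Y725F (mean 0.00, fry adjusted p 0.0253) against TagRFP, and with the covariate 0.23 and 0.18 (0.447 and 0.802). Without the low-count filter they were 0.15 and 0.21 (0.447 and 0.975), under median-of-ratios scaling -0.26 and -0.43 (0.0271 and 0.0092), with the replicate number as a block -0.15 and -0.41 (0.286 and 0.0737), and in limma with a trend -0.18 and -0.48 (0.662 and 0.0876). For genes induced by a log2 fold change of at least 2 they were -0.02 and -0.11 (0.16 and 0.013). Against Top1WT, Top1Y725F had a median of -0.28 over all LPS-induced genes (mean -0.09, fry adjusted p 0.203). Without TagRFP 1, TagRFP 2, Top1WT 1 or Top1WT 2, the Top1WT median was -0.24, -0.22, -0.33 and -0.05. Without TagRFP 1, TagRFP 2, Top1Y725F 1 or Top1Y725F 2, the Top1Y725F median was -0.54, -0.51, -0.56 and -0.41, with fry adjusted p-values of 0.134, 0.0988, 0.175 and 0.203. Without TagRFP 1, TagRFP 2, Top1WT 1 or Top1WT 2, the Top1WT count was 112, 154, 3265 and 141. Without TagRFP 1, TagRFP 2 or Top1Y725F 2, the Top1Y725F count was 3126 (852 higher, 2274 lower), 3279 (986 and 2293) and 5754. For Top1Y725F against Top1WT it was 1, 43, 1 and 1 without Top1WT 1, Top1WT 2, Top1Y725F 1 or Top1Y725F 2.

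**Figure D4:**
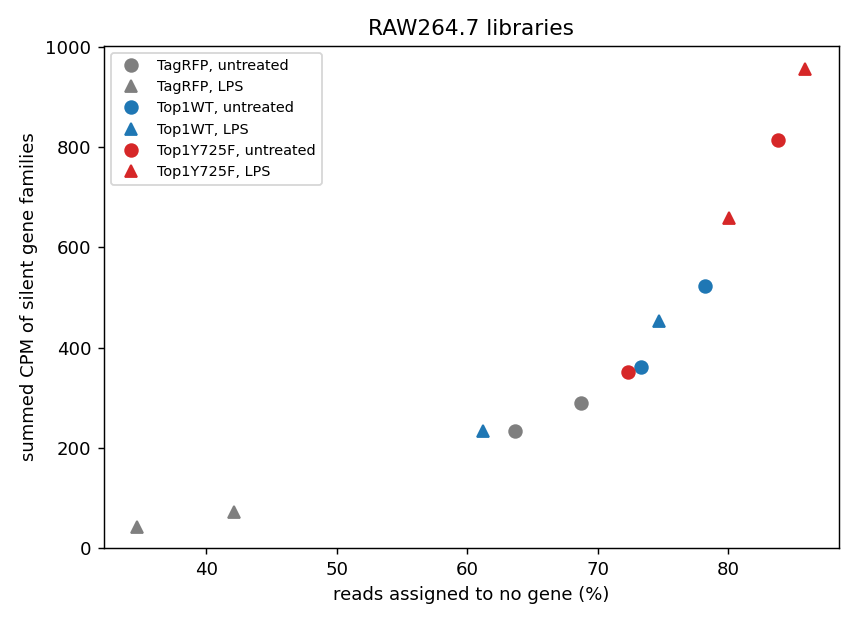
Summed CPM of 471 genes from families silent in macrophages (y axis) against the percentage of reads assigned to no gene (x axis) in the 12 RAW264.7 libraries, coloured by construct, with circles for untreated and triangles for LPS. The values rise together from 43.1 CPM at 34.7% to 956 CPM at 85.9%.

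The log2 response to LPS was lower with Top1WT than in TagRFP cells for 139 genes and higher for 82, 221 in all. Under median-of-ratios scaling 293 were lower and 76 higher. A higher value can also be a smaller fall, and a lower value a larger fall. Without the low-count filter 71 were lower and 68 higher. With the share of reads in no gene as a covariate, chosen after seeing the data, 35 were lower and 95 higher. The response was lower for 10 of 23 cell cycle genes, 18 adjusted over the list alone (fry adjusted p 0.0262). It was lower for 5 of 17 cytokines, 11 adjusted over the list alone (fry adjusted p 0.0135). The response with Top1Y725F differed from that with Top1WT in 0 genes by limma-voom (1007 at an unadjusted p under 0.05) and in 0 by limma with a trend. The former count was 36, 70, 65 and 60 without TagRFP 1, TagRFP 2, Top1WT 1 or Top1WT 2 untreated, and 127, 64 and 126 without TagRFP 1, TagRFP 2 or Top1WT 1 with LPS. Without Top1WT 1, Top1Y725F 1 or Top1Y725F 2 untreated the latter count was 1, 6 and 7. Median-of-ratios scaling moved the median of all genes by 0.11 in the TagRFP response, by 0.13 for Top1Y725F against Top1WT with LPS, and by -0.14 and 0.13 in the differences of responses.

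In E3C3 cells few genes passed the threshold. With Top1WT, LPS called 13 of 15248 genes, 10 higher and 3 lower. DUSP8 rose from 50.5 ± 1.4 to 106 ± 6.47 CPM (log2 fold change 1.07, SE 0.16, adjusted p 0.000671), and CIC from 129 ± 3.64 to 205 ± 1.14 CPM, while MND1 fell from 48.2 ± 3.91 to 23.2 ± 0.218 CPM. With LPS, Top1Y725F against Top1WT called 9 genes, 0 higher and 9 lower. TLR4 was 11900 ± 692 CPM with Top1Y725F and 20000 ± 3620 CPM with Top1WT (log2 fold change -0.74, SE 0.08, adjusted p 1.32e-06). LPS acts through TLR4, so the groups also differed in RNA of the LPS receptor. This comparison cannot separate that difference from an effect of Top1Y725F on the LPS response. ALPK3 was 16.8 ± 4.78 with Top1Y725F against 49.3 ± 0.218 CPM with Top1WT. TOP1 stood at 188 ± 16.4 CPM untreated, at 193 ± 21 CPM with LPS and at 160 ± 9.15 CPM with Top1Y725F. Without Top1WT 1 or Top1WT 2 untreated, the LPS count was 29 and 53. Without Top1WT 2 with LPS or Top1Y725F 1 with LPS, the other count was 25 and 20. With the replicate number as a block the counts were 75 and 41, and the LPS count was 3 without the low-count filter and 7 in limma with a trend.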

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

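The following values stood apart from the rest. Of 92 groups of values examined, 2 held a value far outside the others, against 4.6 expected by chance at 1 in 20. Il12a was 2.42 CPM in untreated WT replicate 4, against 0 to 0.743 CPM in the other untreated WT libraries. WT replicate 2 with LPS held 31.0 M (M, mega) counts in genes, against 14.6 to 16.6 M in the others of its group. The response to LPS differed between KO and FL in 285 genes and the response to PolyIC in 38, and in RAW264.7 the response to LPS differed between Top1WT and TagRFP in 221.

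Tests of the explanations below were set out before they were run, except that the tests of the Top1 transgene and of the share of macrophages were chosen after seeing the result. Untreated KO and FL differed in 1289 genes in the takara-labelled libraries and in 0 in the others. An effect of the takara-labelled cultures alone would leave signs unrelated, and 88.8% of the genes had the same sign in the other libraries. A larger spread between replicates could account for the lack of calls, and the median standard error was 2.02 times that of the takara-labelled libraries. This ratio covers only genes called in the takara-labelled libraries, and a call favours a small standard error there. The selection alone can raise the ratio, so it does not decide this. The genes were chosen by their takara calls, so their smaller effects in the other libraries decide nothing on this.

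In untreated KO cells, 10 of 18 macrophage identity genes were called lower and 1 higher, and 3 of 13 stromal markers were called higher (fry adjusted p 0.13). These 3, Kdr, Pecam1 and Cdh5, are endothelial genes. Emcn and Plvap, also endothelial, were among the 4 genes called higher in KO with Imiquimod in the other libraries. A smaller share of macrophages alone would lower all identity genes alike, if no other cells expressed them. Their log2 fold changes ran from -2.43 (Lyz2) to 0.50 (Cebpb), 20 median standard errors apart. A smaller share together with changes of single genes remains possible, and this range cannot exclude it. Lyz2 carries Cre in this line, so its own fall could come from the insertion, and without it the range was 18.5 median standard errors. Neutrophil markers had a median of -1.96 and 12 of 13 stromal markers lay above 0, so other cell types may still differ. A stretch of DNA carried along with the Cre insertion would place called genes near Lyz2, and the share called there was 1.02 times the share elsewhere.

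In RAW264.7 cells with LPS, Top1Y725F and TagRFP differed in 9520 genes. Across the 12 libraries, genes of families silent in macrophages rose with the share of reads in no gene (Spearman rho 1, permutation p 1e-05), which could come from genomic DNA in the libraries. Counts taken up by Top1 were at most 7.6% of a library with Top1Y725F and LPS. They can shift other genes by at most 0.11 on the log2 scale. Of the other called genes, 99.6% moved past this by over 2 standard errors. A called gene already lies over 2 standard errors from 0, so this share was nearly fixed in advance and decides nothing. An earlier test, the count of genes called untreated, changed too much without 1 library to decide. LPS-induced genes had a median of -0.49, and random genes of matched expression had -0.60 (95% of lists from -0.65 to -0.56), so the induced genes fell less than matched genes, and a fall of all expressed genes could account for theirs but was not settled. These libraries cannot separate an effect of Top1Y725F on the LPS program from background.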

How the results depend on the processing

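Of the alternatives run, 425 left the result the same, 130 moved a count by more than 1.5-fold or across 0, and 25 reversed the sign of a median. With the sign kept, 6 took the fry adjusted p, or the permutation p for gene length, from under 0.05 to above it. Another 4 took it the other way. Neither label concerns the size of the median. Many results that stayed the same were 0 called genes in both fits, which says little about stability. The planned DESeq2 alternatives were not run, and the planned edgeR test was replaced by limma-voom. Where a group was left with 1 library, its spread was taken from the other groups. Under median-of-ratios scaling, the difference of LPS responses between Top1WT and TagRFP was 369 (221), and the LPS-induced median with Top1WT -0.26 (fry adjusted p 0.0271). Without the low-count filter, untreated RAW264.7 counts were 12 for Top1WT, 18 for Top1Y725F and 3 between them, Top1WT with LPS 2746, the response difference 139 and LPS in E3C3 3, and induced medians were 0.03 (PolyIC), 0.15 (Top1WT) and 0.21 (Top1Y725F). With a block for the replicate number, the KO differences of response were 480 (LPS) and 107 (PolyIC), and KO against FL in the other libraries 10 untreated, 12 with Pam3CSK4, 17 with FSL and 74 with Imiquimod. WT counts were 4559 with FSL and 3161 with Imiquimod, topotecan without agonist 1937, and topotecan differences 722 (LPS), 30 (FSL) and 38 (Imiquimod). Same-number correlations were 0.751 (topotecan with FSL), 0.779 (topotecan with Imiquimod) and 0.594 (Pam3CSK4 against FSL), and 2 pairs do not settle pairing. For topotecan without agonist they were -0.126 and -0.147, and for FSL and Imiquimod against untreated WT -0.242 to -0.049. Another number reached 0.417 to 0.525 there, which argues against pairing by number with the untreated WT libraries. Top1Y725F against Top1WT with LPS was 15, and E3C3 counts 75 and 41. Induced medians were 0.00 (untreated KO), 0.05 (Pam3CSK4), 0.01 (Imiquimod) and -0.41 (Top1Y725F, fry adjusted p 0.0737). With limma and a trend on log2 CPM, chosen after seeing the data, counts were 7 for KO with Imiquimod, 93 for Imiquimod in FL, 14 for untreated Top1Y725F, 3 for untreated Top1Y725F against Top1WT, 3181 for Top1WT with LPS, 2 for Top1Y725F against Top1WT with LPS and 7 for LPS in E3C3, and medians 0.00 (untreated KO) and -0.48 (Top1Y725F, fry adjusted p 0.0876). With induced genes defined at a log2 fold change of 2, medians were 0.04 (PolyIC), 0.06 (untreated), 0.05 (Pam3CSK4), -0.02 (Top1WT) and -0.11 (Top1Y725F). With untreated WT replicates 1 to 4, Imiquimod called 211, topotecan without agonist 2 and its difference with LPS 1, and the Pam3CSK4 median was 0.01. With replicates 5 and 6, FSL called 304 and Imiquimod 38. Both kinds of FL and KO library in 1 fit called 48. With the share of reads in no gene as a covariate, also chosen afterwards, RAW264.7 counts were 146 for LPS in TagRFP, 18, 2 and 11 untreated, 7, 1 and 0 with LPS and 130 for the response difference, and induced medians 0.23 (Top1WT) and 0.18 (Top1Y725F). With a block over the compared groups, chosen afterwards too, topotecan called 7 with FSL and 451 with Imiquimod, and the FSL median was -0.08 (fry adjusted p 0.0211). With 1 library left out in turn, KO against FL in the takara-labelled libraries called 487 to 736 untreated, 784 to 1470 with LPS and 713 to 1406 with PolyIC, and the response differences 109 to 373 and 3 to 55. In the other FL and KO libraries, the ranges were 0 to 3 untreated, 0 to 11 with FSL and 0 to 2 with Imiquimod, 70 to 260, 157 to 647 and 0 to 599 for the responses to Pam3CSK4, FSL and Imiquimod, 0 to 3 for Pam3CSK4 against FSL and 0 to 1 for the FSL difference. WT ranges were 4003 to 5102 with LPS, 192 to 1191 with FSL and 20 to 145 with Imiquimod, and every topotecan count stayed 0. RAW264.7 ranges were 522 to 903 for LPS in TagRFP, 1 to 6, 3 to 3654 and 1 to 373 untreated, 112 to 3265, 3126 to 8357 and 1 to 43 with LPS, and 36 to 158 and 0 to 7 for the differences. E3C3 ranges were 10 to 53 and 8 to 25. Induced medians ran from -0.24 to -0.06 (KO with LPS, fry adjusted p 0.0126 at the lowest median), -0.02 to 0.02 (PolyIC), -0.03 to 0.02 (untreated), -0.26 to 0.23 (Pam3CSK4), -0.42 to 0.09 (FSL) and -0.95 to 0.40 (Imiquimod). For topotecan they ran from -0.23 to 0.06 with LPS, -0.39 to 0.15 with FSL, -0.48 to -0.21 with Imiquimod and 0.03 to 0.09 without agonist, and in RAW264.7 from -0.33 to -0.05 for Top1WT, -0.56 to -0.41 for Top1Y725F and -0.42 to -0.15 between them. The gene-length difference ran from -0.30 to -0.16 and the correlation of KO and topotecan effects from 0 to 0.298.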

Other observations

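Some results bear on the design rather than on a comparison. Among 100 groupings of the untreated and LPS-treated WT libraries, only the real grouping reached 4988 called genes, and the next highest called 991. For topotecan with LPS the real grouping called 0 genes, so all 35 groupings called as many by necessity and their number decides nothing about chance. The grouping with the highest count, replicates 1 and 2 against 3 and 4, called 1994, which points to a structure of these libraries by replicate number.

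Within 10 Mb of Lyz2 on chromosome 10, 8 of 73 genes were called in untreated KO cells (11%, against 10.7% of the others), and with LPS and PolyIC the ratio of shares was 0.81 and 1.00.

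LPS in WT cells called 36.2% of all genes tested, so calls within a list are not specific to it. Of the 8 genes in the topoisomerase list, 1 rose (Top1) and 3 fell (Top1mt, Tdp2, Tdp1), the same numbers adjusted over the list alone (fry adjusted p 0.00341). Tdp2 and Tdp1 are in this list but are not topoisomerases. Of 21 SWI/SNF subunits, 8 rose and 2 fell (Smarca2, Arid1b), the same numbers adjusted over the list alone (fry adjusted p 8.17e-05).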
